A study of Drosophila melanogaster with 14 samples.

How the data were processed

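The series profiled 4 insulator proteins by chromatin immunoprecipitation and sequencing (ChIP-seq) in Kc167, a cell line from Drosophila melanogaster embryos. Cells were sampled untreated (0 h) and after 3 and 48 h with 5e-07 M 20-hydroxyecdysone, the steroid hormone that drives moulting and metamorphosis in flies. There were 14 samples: 12 ChIP libraries, 1 for each protein and time, and 2 input libraries of untreated cells, which were not analysed here.

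Each ChIP library had 1 deposited peak list with 5 columns: sequence name, start, end, peak name and a score per peak. The peak names carry the prefix of the MACS peak caller, per the files themselves. Reads were aligned with Bowtie 0.12.5, per the submitters' processing notes. The version and settings of the caller, the control used, the aligner settings and the genome build are not given in the sources used here. The sequence names, among them U, Uextra and the heterochromatic pieces ending in Het, are those of Release 5 of the genome. Coordinates are given as deposited, counted from 1.

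The score in the deposited lists is the authors' own value for each peak, and its definition is not given in the sources used here. The lowest score was 100.0 and many peaks stood at exactly 3100, with 488 of 81028 peaks above it, up to 3233.06. Scores of 3100 or more were treated as tied, a choice made after the values were seen, and ties were ordered by width and then by position. Scores were used to describe, rank or filter peaks within their own list. The fixed score classes are the exception, since they have the same limits in every list. The read depth of the libraries is unknown, since the lists hold no counts. Of the peaks, 2 had a start below 0 and were kept as deposited.

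Peaks of 2 lists were called shared when they overlapped by at least 1 bp. A 0 h peak was persistent when it overlapped a peak of the treated list of the same protein. A treated peak was gained, and a 0 h peak lost, when the other list had no peak within 1 kb, so a few peaks were neither shared nor gained or lost. For the 3 time points, the peaks of a protein were merged into regions and each region was classed by the times at which it held a peak: a transient gain at 3 h only, a late gain at 48 h only and a lasting gain at 3 and 48 h. Shares carry 95% Wilson intervals, which cover counting error only. Score-matched shares carry no interval of their own. The share given by chance was the mean of 200 random placements of the peaks within their own sequence. Draws of peaks from a list numbered 10000, or 1000 for pairs of lists and for windows of 100 kb. The main arms were X, 2L, 2R, 3L, 3R and 4, and unplaced sequence was U and Uextra.

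Each protein and time had 1 library, so there were no replicates, no test between times was run, and percentiles among draws describe these libraries alone. With the 3 lists of a protein, both treated lists are compared with the same 0 h list. Beside classes that depend on it, the mean of the 3 classes of the same kind is given, the value expected if the lists were exchangeable. The overlap of independent lists, from the product of their gained counts divided by the number of regions, is given too.

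The rule for naming peaks, fixed before the data were examined, took the 5 gained and the 5 lost peaks with the highest score for each protein and treated time, plus the 5 windows of 50 kb with the most gained peaks. The same rule on the main arms alone was added after the data were seen, because many leading peaks lay on unplaced sequence, and most peaks named here come from it. Positions in genes, lists of ecdysone-responsive and other genes, and DNA motifs had been planned for use with an annotation and a genome of the build of the lists. These were not used here, so no gene names are given and those parts were not run.

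The alternatives set before the data were examined were an overlap of 50% of the shorter peak, peak centres within 250 bp, no overlapping peak in place of the distance of 1 kb, the top 50% of each list by score, lists shortened to equal length by score, merging of peaks less than 200 bp apart, the main arms alone, matching on score deciles and windows of 100 kb. Added after the data were seen were the arms alone for co-occupancy, for the classes over time and for changed CP190 peaks, score-matched draws for gains of 1 protein at gains of another, score-matched draws of windows (2000 draws), and score matching for gained BEAF-32 peaks and for high-scoring gained CP190 peaks, on all sequences and on the arms. In all, 263 alternative values were computed.

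The overlap code was tested on simulated lists of 6000 sites with 700 gained and 400 lost sites, in 5 runs, and recovered 100% of the gained, lost and persistent sites. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.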

Results

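The series asked how the distribution of insulator proteins over the genome changes when Kc167 cells receive 20-hydroxyecdysone. CP190 is a zinc-finger protein that joins insulator complexes through DNA-binding partners. Su(Hw), which binds the gypsy insulator, dCTCF, the fly counterpart of vertebrate CTCF, and BEAF-32, a boundary element factor, are such partners. Each was mapped at 0, 3 and 48 h in 1 library per time, without replicates.

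CP190 had 6691 peaks at 0 h, 7301 at 3 h and 6708 at 48 h. Su(Hw) had the longest lists, with 7972, 8514 and 8352 peaks. dCTCF had 5600, 5352 and 5037 peaks, and BEAF-32 had 6135, 6830 and 6536. On the main arms, BEAF-32 peaks numbered 4187 at 0 h, 5882 at 3 h and 5896 at 48 h, while dCTCF peaks numbered 4003, 4085 and 3333. On unplaced sequence, BEAF-32 had 1818, 782 and 486 peaks and dCTCF had 1526, 1205 and 1642. CP190 had 912, 981 and 977 peaks there, and Su(Hw) had 9, 10 and 9. The median peak width lay between 505 bp, for dCTCF at 0 h, and 1070 bp, for CP190 at 3 h.

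**Figure D1:**
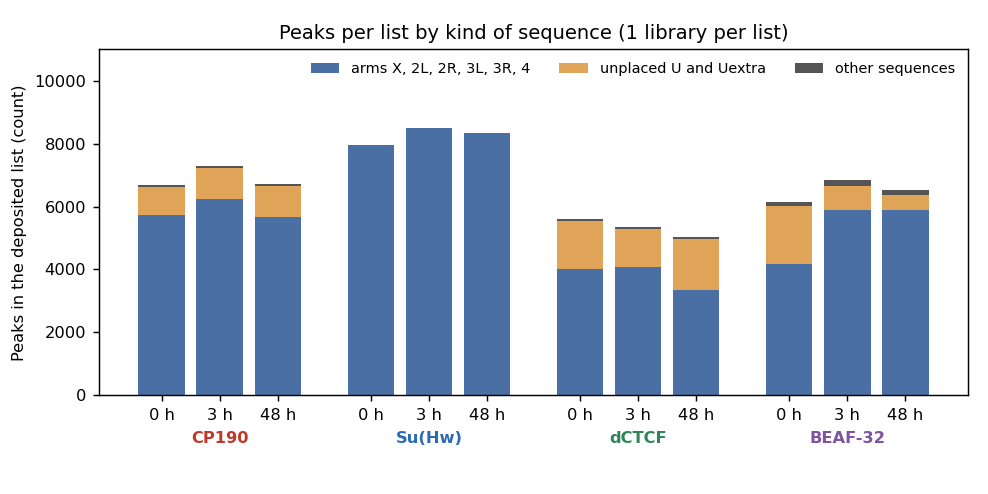
Bars give the number of peaks in each of the 12 deposited lists (vertical axis, count) by protein and time (horizontal axis), stacked by main arms, unplaced sequence and other sequences. BEAF-32 at 0 h has 1818 unplaced peaks against 486 at 48 h, and Su(Hw) has almost none.

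The first comparison asked which binding sites of each protein stayed, appeared or disappeared. Most CP190 and Su(Hw) sites stayed: 95.2% of 0 h CP190 peaks (95% interval 94.7 to 95.7) and 92.45% of Su(Hw) peaks (91.8 to 93.0) overlapped a 3 h peak, and 88.55% and 88.6% overlapped a 48 h peak. For dCTCF the shares were 81.5% at 3 h and 81.7% at 48 h. For BEAF-32 they were 74.6% (73.5 to 75.7) and 70.1% (68.9 to 71.2). Random placement gave between 3.95% and 10.3%.

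Unplaced sequence held 72.8% of the BEAF-32 peaks lost at 3 h and 76.6% of those lost at 48 h. On the arms, 90.4% of 0 h BEAF-32 peaks (89.4 to 91.2) persisted at 3 h and 90.0% (89.1 to 90.9) at 48 h. CP190 peaks on the arms persisted at 96.4% and 89.1%, and dCTCF peaks at 84.7% and 77.6%. Every 0 h arm peak with a score at the ceiling was present at both treated times, for each of the 4 proteins: 1079 peaks of CP190, 2748 of Su(Hw), 1217 of dCTCF and 1497 of BEAF-32. Weak peaks differed most. Among 0 h arm peaks with a score under 200, 83.1% of CP190, 69.7% of Su(Hw), 53.7% of dCTCF and 68.7% of BEAF-32 peaks were found at 3 h. At 48 h the shares were 57.5%, 59.75%, 35.5% and 66.4% in the same order, so BEAF-32 stood highest. Whether a score means the same in each list is unknown.

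The order of the proteins depended on the length of the lists and on the sequences counted. With all lists at 5037 peaks, Su(Hw) persisted most at 3 h, with 94.2% (93.5 to 94.8), ahead of CP190 with 91.2% (90.4 to 91.9), dCTCF with 84.3% and BEAF-32 with 73.5%. With 3333 arm peaks per list, the 3 h shares were 96.9% for Su(Hw), 93.3% for CP190, 87.8% for BEAF-32 and 86.3% for dCTCF. The intervals of the last pair overlapped. In the same order, the whole 0 h arm lists held 7951, 5720, 4187 and 4003 peaks. The cut thus kept the smallest part of the longest list, and stronger peaks persisted more, so it favours the longer lists.

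CP190 gained 905 peaks and lost 286 at 3 h, when its list was longer, but 579 and 501 with its lists at equal length. At 48 h it gained 707 and lost 684. Su(Hw) gained 773 and lost 460 at 3 h, then gained 984 and lost 703 at 48 h. At equal length it gained 527 and lost 606 at 3 h, and gained 803 and lost 825 at 48 h. dCTCF gained 677 and lost 844 at 3 h, and gained 496 and lost 918 at 48 h, with 250 of those gains and 809 of those losses on the arms. At equal length dCTCF gained 689 and lost 649 at 3 h, and gained 632 and lost 574 at 48 h. BEAF-32 gained 1897 peaks and lost 1422 at 3 h, and gained 1926 and lost 1724 at 48 h. With its lists at equal length, gains numbered 1446 and losses 1570 at 3 h, and 1697 and 1864 at 48 h. Lists of equal length force gains and losses close together, so such counts do not show a net gain or loss. On the arms BEAF-32 gained 1800 and 1833 peaks and lost 363 and 375. Gained peaks were mostly weak: none of those of CP190 or Su(Hw) at 3 h ranked in the top 50% of its list by score. At 48 h, 24 gained CP190 peaks and 23 gained Su(Hw) peaks did.

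**Figure D2:**
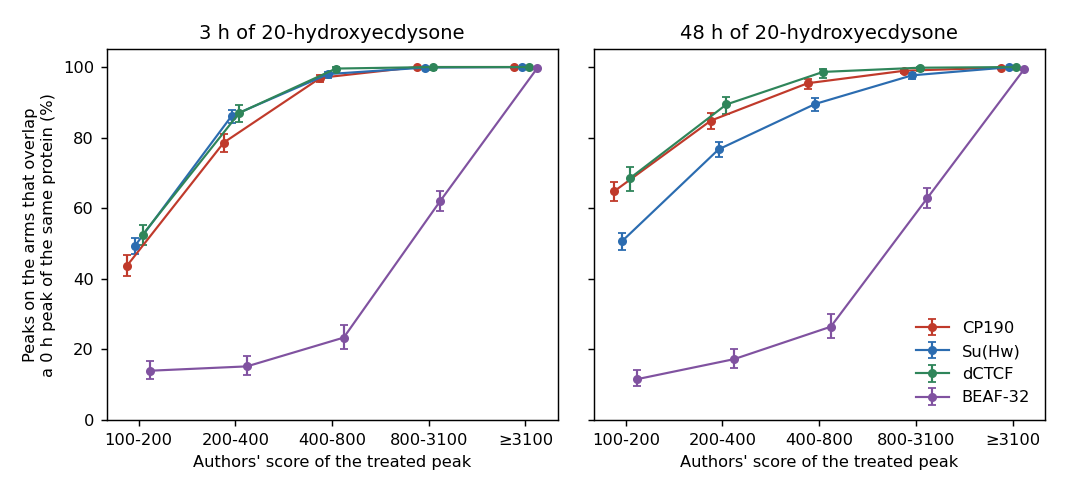
Points give the share of treated peaks on the main arms that overlap a 0 h peak of the same protein (vertical axis, %) by the authors' score of the treated peak (horizontal axis, 5 classes), at 3 h and 48 h, with 95% Wilson intervals as bars. For BEAF-32 the share is 13.9% in the lowest class at 3 h, 62.1% from 800 to 3100 and 99.6% at the ceiling, while CP190 has 43.7%, 100% and 100%.

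The strongest gained CP190 peaks on the arms appeared at 48 h. The peak at 3L:18025463-18026631 reached the score ceiling and lay on a dCTCF peak present at all 3 times and on a Su(Hw) peak present only at 48 h. A second, at 3R:15061154-15062026, also reached the ceiling and overlapped no peak of another protein at any time. Another, at 2R:4316296-4317505 (score 1754.31), lay on a dCTCF peak present at all times. At 3 h the highest-scoring gain was 3L:13220369-13222061 (score 632.72), where Su(Hw), dCTCF and BEAF-32 had peaks at all times and CP190 kept its peak at 48 h. The strongest CP190 loss at 48 h was 3L:23730041-23731335 (score 925.55 at 0 h), which was still present at 3 h.

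Su(Hw) gained 2 peaks at the ceiling at 48 h, 2R:15162687-15163446, where BEAF-32 also had a peak only at 48 h, and 2L:15915798-15916450, where no other protein had one. The peak gained at 3R:16878663-16879511 (score 2511.11) lay on a CP190 peak present at all times. Among the Su(Hw) peaks lost at 48 h, 3L:17943124-17944025 (score 732.44) and 3L:17562975-17563810 (score 727.47) ranked highest. Both were still present at 3 h, when dCTCF had a peak at each that it lacked at 0 and 48 h.

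dCTCF gained a peak at X:17425862-17426198 at 3 h (score 698.2), listed at 48 h as X:17425798-17426236 (score 2103.33), where CP190 had a peak only at 48 h. Its strongest losses at 48 h were 2R:13365045-13365931 (score 2845.09 at 0 h) and 3R:19364497-19365079 (score 2746.51), both present at 3 h. At the first of these CP190 was present at 0 and 3 h and absent at 48 h, and at the other CP190 and Su(Hw) peaks were present at all times. The dCTCF peak at 2L:21296179-21296836 (score 1754.35) was absent at 3 and 48 h, and CP190 had a peak there only at 48 h.

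BEAF-32 gained 8 arm peaks at the ceiling at 3 h and 12 at 48 h. The peak 3L:9422025-9423783 and the peak 3R:5503274-5504277 appeared at 3 h, were present at 48 h, and lay where CP190, Su(Hw) and dCTCF had peaks at all times. At 3L:1617698-1618784, gained at 3 h and present at 48 h, CP190 had peaks at 0 and 3 h only. The arm peak 2L:14706175-14706827 (score 1893.19) was lost at both times, and the other 3 proteins had peaks there throughout. Over all sequences, the 5 highest-scoring BEAF-32 losses at either time lay on U or Uextra, led by U:2190356-2199546 at the ceiling.

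The second comparison followed regions over the 3 times. Regions bound at all 3 times made up 71.9% of 7974 CP190 regions, 69.1% of 9759 Su(Hw) regions, 59.6% of 6662 dCTCF regions and 47.65% of 8668 BEAF-32 regions (46.6 to 48.7). CP190 had 585 transient, 386 late and 430 lasting gains, Su(Hw) had 617, 843 and 474, and dCTCF had 625, 450 and 144. BEAF-32 had 407 transient, 469 late and 1754 lasting gains. On the arms 1679 BEAF-32 regions were bound at 3 and 48 h but not at 0 h, whereas 50 were bound at 0 and 3 h only and 33 at 0 and 48 h only. The mean of those 3 classes is 587.3. Of the 1800 BEAF-32 arm peaks gained at 3 h, 1457 (80.9%, 79.1 to 82.7) were gained at 48 h as well, beside 526.9 for independent lists. For CP190 the count was 267 of 727 (36.7%), beside 57.8 for independent lists, for Su(Hw) 345 of 767 (45.0%), beside 80.0, and for dCTCF 93 of 592 (15.7%), beside 34.0. Lasting gains on the arms numbered 309 for CP190, 470 for Su(Hw) and 108 for dCTCF, with class means of 273.7, 378.7 and 242.0. In the same order, 457, 483 and 457 regions were bound at 0 and 3 h only, more than the lasting gains. Those bound at 0 and 48 h only numbered 55, 183 and 161. Gains at both times are defined by absence from the same 0 h list, so an excess over independent lists is to be expected. How much of each excess comes from that shared list could not be split.

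**Figure D3:**
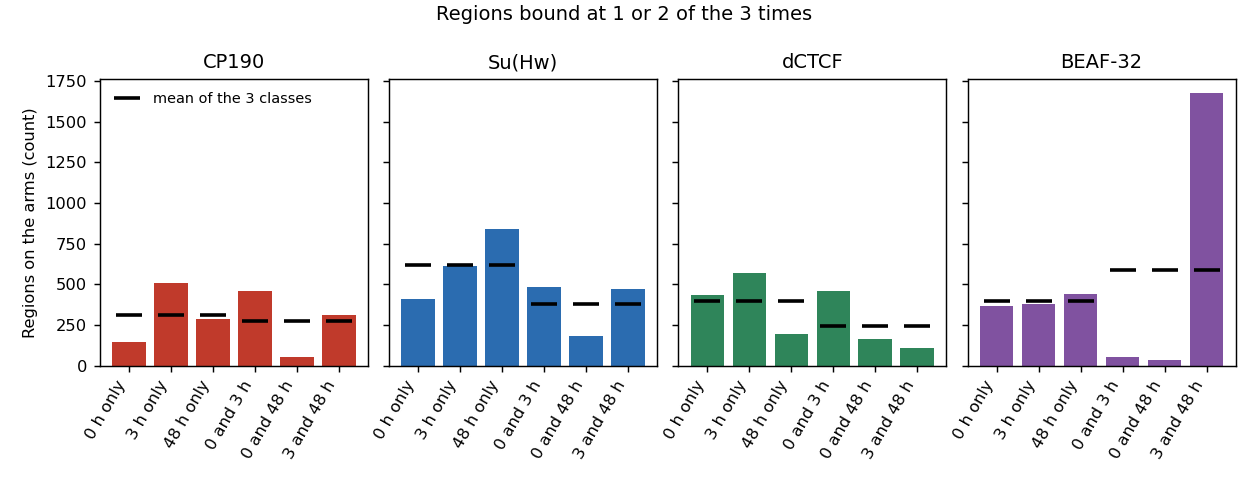
Bars give the number of regions on the main arms (vertical axis, count) bound at only 1 or only 2 of the 3 times (horizontal axis) for each protein, and black lines give the mean of the 3 classes of the same kind. BEAF-32 has 1679 regions in the class of 3 and 48 h, beside a mean of 587.3.

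The third comparison asked where CP190 lay relative to its partners. At 0 h, 55.2% of CP190 peaks (54.0 to 56.4) overlapped a Su(Hw) peak, 50.4% (49.2 to 51.6) a dCTCF peak and 51.25% (50.05 to 52.4) a BEAF-32 peak, and 88.4% overlapped at least 1 of the 3. The share with Su(Hw) was 54.6% at 3 h and 54.9% at 48 h. The share with dCTCF was 45.6% (44.4 to 46.7) and then 44.0% (42.9 to 45.2), and the share with BEAF-32 was 52.95% (51.8 to 54.1) and then 48.7% (47.5 to 49.9). On the arms, the share with BEAF-32 was 48.4% (47.1 to 49.7) at 0 h, 57.0% (55.8 to 58.3) at 3 h and 54.8% (53.5 to 56.1) at 48 h, and with dCTCF 47.15%, 42.5% and 39.05%. These shares follow the number of partner peaks in each list as well as their place. Random placement gave 5.26% to 10.9% over all sequences.

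Regions of the arms with all 4 proteins numbered 1359 of 11734 at 0 h (11.6%, 11.02 to 12.2), 1448 of 12699 at 3 h (11.4%) and 1252 of 12708 at 48 h (9.85%, 9.35 to 10.4). Regions with 1 protein made up 53.0%, 47.2% and 52.1%.

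Gained CP190 peaks had partners less often than persistent ones. At 3 h, 38.9% of gained CP190 peaks (35.8 to 42.1) overlapped a Su(Hw) peak, against 57.4% of persistent peaks. With dCTCF the shares were 22.2% and 49.3%, and with BEAF-32 43.65% and 54.3%. At 48 h the gained peaks had 40.2% with Su(Hw), 22.5% with dCTCF and 24.6% with BEAF-32, against 57.2%, 46.9% and 52.2%. None of 10000 draws of as many CP190 peaks gave shares as low. Gained peaks were weaker, and beside persistent peaks of the same score the difference for Su(Hw) turned round, to 7.13 percentage points more at 3 h and 4.42 more at 48 h. On the arms it was 9.19 more at 48 h, and at 3 h 2.38 more, where the matched share of 45.6% lay within the interval of the gained peaks (44.4 to 51.6). For dCTCF it stayed lower, by -8.7 and -8.33 points. For BEAF-32 it was -1.49 points at 3 h, where the matched share of 45.1% lay within their interval (40.45 to 46.9), and -28.29 at 48 h. On the arms the BEAF-32 difference was -7.89 at 3 h, with the matched share of 53.4% above the interval (41.9 to 49.2), and -36.48 at 48 h.

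Gains of 1 protein lay on gains of another between 13 and 120 times per pair of proteins and time. Gained CP190 peaks lay on gained dCTCF peaks 27 times at 3 h, with 54.3 in draws and 34.9 in score-matched draws. At 48 h they did so 13 times, with 31.5 and 19.3. Gained Su(Hw) peaks lay on gained dCTCF peaks 38 times at 3 h, with 29.0 in draws and 38.8 in score-matched draws. At 48 h they did so 16 times, with 24.5 and 37.4. At 48 h, 38 gained CP190 peaks lay on gained BEAF-32 peaks, where draws gave 104.0 on average and score-matched draws 66.4. At 3 h the count for this pair was 0.73 times the 137.4 of draws and 1.03 times the 98.3 of score-matched draws. Gained CP190 peaks lay on gained Su(Hw) peaks 28 times at 3 h, fewer than the 47.9 of draws and more than the 20.85 of score-matched draws, whose highest was 36. At 48 h they did so 18 times, with 48.3 in draws and 22.3 in score-matched draws. Gained Su(Hw) peaks lay on gained BEAF-32 peaks 88 times at 3 h, with 65.7 in draws and at most 90, and 115 times at 48 h, with 84.8 in draws and 99.0 in score-matched draws, whose highest was 127. Gained dCTCF peaks lay on gained BEAF-32 peaks 120 times at 3 h, with 97.5 in draws and at most 122. At 48 h they did so 62 times, with 62.1 in draws and 41.1 in score-matched draws, whose highest was 58. All sequences were counted together here, although unplaced sequence held 47.4% of the dCTCF gains at 48 h and 2.44% of the BEAF-32 gains.

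The fourth comparison asked where on the arms the gained peaks lay. In windows of 50 kb the densest cluster was formed by Su(Hw) at 48 h: 8 gained peaks between 17950001 and 18000000 on 3L, where 13 Su(Hw) peaks were listed against 7 at 0 h and 2 were lost. Of the 8 peaks, 3 were already present at 3 h, among them 3L:17998399-17999276 (score 512.75), and the highest-scoring, 3L:17957605-17958454 (score 620.33), was absent at 3 h. Of 10000 draws of as many Su(Hw) peaks, 10 (0.1%) had a window as full, among 8 combinations of protein and time examined. In windows of 100 kb the maximum of Su(Hw) at 48 h was again 8, which 4.4% of draws reached, while BEAF-32 had up to 11 gained peaks at 3 h and 9 at 48 h, which 12.6% and 76.6% of draws reached. CP190 at 48 h had 5 gained peaks between 13550001 and 13600000 on 3L, a count that 1.06% of draws and 3.1% of score-matched draws reached. In windows of 50 kb, for the other 6 combinations, 18.4% or more of the draws had a window as full.

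**Figure D4:**
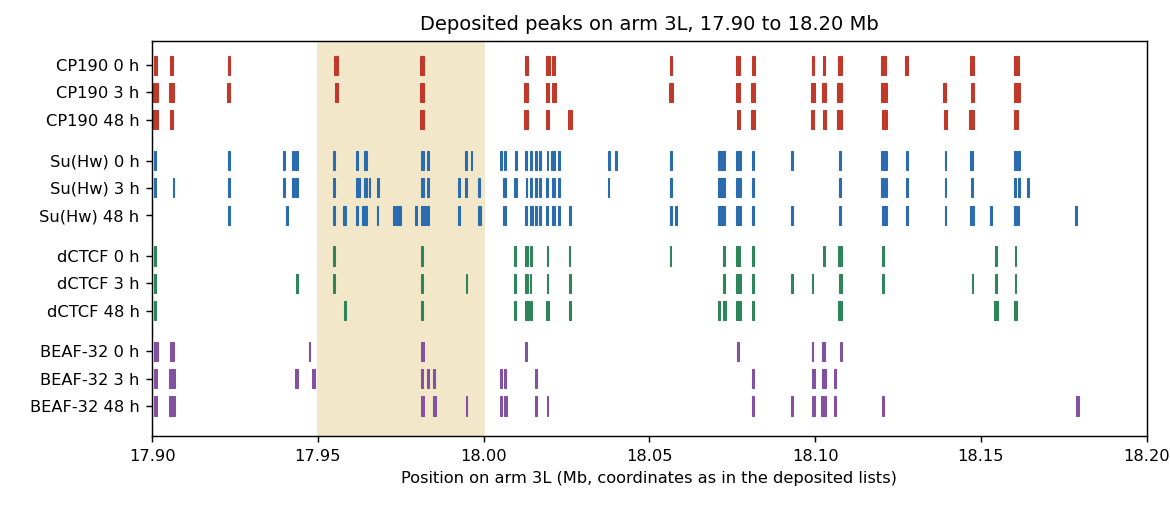
Rectangles mark every deposited peak in the 300 kb of arm 3L that start at 17900001 (horizontal axis, position in Mb), to scale, with 1 line for each protein and time, and the shaded band is the window with 8 gained Su(Hw) peaks. Su(Hw) has 7 peaks in the band at 0 h, 11 at 3 h and 13 at 48 h.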

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

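The tests of list sensitivity, unplaced reads, local rise, signal shared between antibodies and Su(Hw) sites on the arms were chosen only after the results were seen.

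Between 0 and 48 h, dCTCF and BEAF-32 moved in opposite directions. On the main arms the number of dCTCF peaks changed by -670 and that of BEAF-32 by 1709, and on unplaced sequence dCTCF changed by 116 and BEAF-32 by -1332. With 1 library each, these differences were not tested.

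The BEAF-32 regions bound at 3 and 48 h but not at 0 h were weighed first. A 0 h list of lower sensitivity cannot be told apart from new weak sites: 0.29% of the 3 h BEAF-32 peaks at the score ceiling were gained, against 27.8% of the whole list, but CP190, Su(Hw) and dCTCF also had 0 gained peaks at the ceiling at 3 h. Reads taken by unplaced sequence remain open: over the 12 lists, deviations from the protein mean in unplaced and arm peaks had r = -0.82 (exact permutation p = 0.0802) and rho = -0.68 (exact permutation p = 0.1173), with r = -0.59 without BEAF-32 at 0 and 48 h and r = -0.48 without BEAF-32. Of gained 3 h BEAF-32 peaks, 37.4% lay on a 0 h CP190 peak, beside 40.7% of persistent peaks of the same score (38.9% and 59.6% on the arms). By the rule set down before the result, this counts against a preference above that of persistent peaks, but the matched share carries no interval. Persistent peaks are defined by a 0 h BEAF-32 peak, and 66.3% of 0 h BEAF-32 arm peaks overlapped CP190. The comparison therefore cannot decide whether BEAF-32 was recruited to sites held by CP190. The same limit holds for Su(Hw), where the answer also depends on the sequences counted. Over all sequences it was 35.3% beside 20.3%, which taken alone would favour recruitment, but on the arms 37.1% beside 45.2%. The test on the arms was chosen after the former was seen, because Su(Hw) had 9 of its 7972 peaks on unplaced sequence.

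The cluster of 8 gained Su(Hw) peaks on 3L at 48 h was weighed next. By the rule set down before the result, the draws argue against chance clustering of single peaks. Of them, 0.1% had a window as full, or 0.35% of 2000 draws matched on score. In windows of 100 kb 4.4% did, and 8 combinations of protein and time were examined. Of the 8 peaks, 3L:17973690-17974402 and 3L:17974461-17975010 lie less than 200 bp apart. The draws counted such neighbours as separate peaks, so chance is not excluded. A local rise of all signal cannot be told apart from a change of Su(Hw) alone: the other 3 proteins together gained 3 peaks there and Su(Hw) lost 2, too few to decide. A response of this region to the hormone is a hypothesis that 1 library per time leaves untested.

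On unplaced sequence, CP190 peaks often lay on peaks of some other antibodies: 70.4% of those at 0 h overlapped a 0 h BEAF-32 peak, against 48.4% on the arms and 7.32% under random placement, and 71.2% overlapped a dCTCF peak, but 0.55% a Su(Hw) peak. Whether this is signal that follows the library and not the antibody stays open. With dCTCF of the same time the share stayed high, at 65.1% at 3 h and 73.7% at 48 h, above the 42.5% and 39.05% on the arms. With BEAF-32 of the same time it was 28.5% at 3 h and 15.25% at 48 h, below the 57.0% and 54.8% on the arms. Yet 75.2% of the 48 h CP190 peaks overlapped a BEAF-32 peak of 0 h. The BEAF-32 lists held 1818, 782 and 486 unplaced peaks at the 3 times, which bounds the BEAF-32 shares. No biological explanation was tested for this pattern.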

How the results depend on the processing

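The arms-only values for co-occupancy, late gains and changed CP190 peaks were chosen only after the results were seen, as was score matching on the arms. Of 263 alternative values, 130 stayed within the interval or within 1.5 times of the reported value, 129 moved further and 4 changed sign. An overlap of 50% of the shorter peak and merging of peaks less than 200 bp apart moved nothing beyond these bounds. The parts on gene lists, positions relative to genes and DNA motifs were not run. No paired analysis was possible because each protein and time had 1 library. Read depth is unknown, so its effect on weak peaks could not be measured. Unless a sentence says otherwise, the cause was not tested, and paired values are for 3 h and then 48 h.

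Matching on score turned the Su(Hw) difference of gained minus persistent CP190 peaks to 7.13 and 4.42 percentage points, and to 2.38 (within the interval) and 9.19 on the arms. Matched differences for gained peaks were -8.7 and -8.33 points with dCTCF and -1.49 (within the interval) and -28.29 with BEAF-32. For lost peaks they were -8.18 and -0.98 (within the interval) with Su(Hw), -14.49 and -14.29 with dCTCF and -12.89 at both times with BEAF-32. Matched on the arms, gained peaks had -4.66 and -11.44 with dCTCF and -7.89 and -36.48 with BEAF-32, all outside the interval. Lost peaks there had -6.02 and -7.45 with Su(Hw), -4.65 and -1.54 with dCTCF and -5.31 and -2.37 with BEAF-32. Among these lost peaks, only the -7.45 lay outside the interval. Unmatched on the arms, gained peaks had -11.88 at 48 h with Su(Hw) and -32.49 and -34.29 with dCTCF, and lost peaks had -10.04 at 48 h with BEAF-32.

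With peak centres within 250 bp, a stricter rule by construction, persistence was 91.0% and 85.0% (CP190), 89.5% and 84.8% (Su(Hw)), 79.9% and 77.5% (dCTCF), and 69.0% and 64.1% (BEAF-32). CP190 co-occupancy at 0, 3 and 48 h was then 49.1%, 46.9% and 47.6% with Su(Hw), 46.5%, 40.4% and 39.8% with dCTCF, and 45.0%, 46.5% and 41.8% with BEAF-32.

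On the arms alone, persistence was 96.4% for CP190 at 3 h, 84.7% and 77.6% for dCTCF, and 90.4% and 90.0% for BEAF-32. Lost peaks numbered 363 and 375 for BEAF-32, 181 for CP190 at 3 h and 518 for dCTCF at 3 h, gained dCTCF peaks at 48 h 250 and late dCTCF gains 192. Co-occupancy of CP190 there was 64.4%, 63.6% and 64.8% with Su(Hw), 47.15%, 42.5% and 39.05% with dCTCF, and 48.4%, 57.0% and 54.8% with BEAF-32.

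With the lists of a protein at equal length, persistence was 91.8% for CP190 at 3 h, 90.25% and 87.0% for Su(Hw), 84.3% and 87.35% for dCTCF, and 72.1% and 68.2% for BEAF-32. CP190 then gained 579 and lost 501 peaks at 3 h, Su(Hw) gained 527 and 803 and lost 606 and 825, dCTCF gained 689 and 632 and lost 649 and 574, and BEAF-32 gained 1446 and 1697 and lost 1570 and 1864. With all 12 lists at the shortest length, it was 91.2% and 87.5% for CP190, 94.2% and 91.4% for Su(Hw), 84.3% and 87.35% for dCTCF, and 73.5% at 3 h for BEAF-32.

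In the top 50% by score, fewer peaks by construction, persistence was 99.8% and 99.6% (CP190), 100% and 100% (Su(Hw)), 98.3% and 99.3% (dCTCF), and 91.7% and 83.0% (BEAF-32). Gained peaks numbered 0 and 24 (CP190), 0 and 23 (Su(Hw)), 4 and 21 (dCTCF), and 126 and 98 (BEAF-32), and lost peaks 5 and 9, 0 and 0, 35 and 16, and 224 and 481 in the same order. Transient, late and lasting gains numbered 0, 20 and 0 (CP190), 1, 23 and 0 (Su(Hw)), 3, 24 and 1 (dCTCF), and 0, 3 and 89 (BEAF-32). For co-occupancy the partner lists were cut to their top 50% as well, so the shares are low by construction. CP190 at 0, 3 and 48 h then had 38.3%, 39.3% and 41.9% with Su(Hw) and 35.1%, 34.3% and 30.4% with dCTCF. With BEAF-32 the shares were 30.9%, 40.45% and 34.2%. Whole 0 h partner lists gave higher shares for the 3320 persistent CP190 peaks in the top 50% at 48 h. These were 73.2% with Su(Hw), 65.5% with dCTCF and 50.4% with BEAF-32.

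With no overlapping peak in place of 1 kb, 31 gained Su(Hw) peaks lay on gained dCTCF peaks at 48 h. In windows of 100 kb, the most gained BEAF-32 peaks at 3 h was 11.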

Other observations

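The test of the CP190 gains was set down before its result was seen, but this set of peaks was picked from the data, and the score-matched and arms-only versions were chosen only after the result was seen.

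BEAF-32 arm peaks that overlapped CP190 numbered 2775 at 0 h, 3703 at 3 h and 3182 at 48 h. As a share of the BEAF-32 arm peaks, which also grew in number, they made up 66.3% (64.8 to 67.7) at 0 h, 62.9% (61.7 to 64.2) at 3 h and 54.0% (52.7 to 55.2) at 48 h. For dCTCF arm peaks the share with CP190 was 71.2% (69.8 to 72.6), 69.5% and 68.4% (66.8 to 69.9), and for Su(Hw) arm peaks it was 48.1%, 50.3% and 46.3%.

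Of the 24 gained CP190 peaks in the top 50% of the 48 h list, 1 covers the mitochondrial genome, with a start listed at -144 and a score of 2743.84. The hypothesis that such peaks form where another protein of the series was bound at 0 h was tested: 17 of the 24 (70.8%, 50.8 to 85.1) lay on such a peak, beside 95.1% of 3320 persistent CP190 peaks of the top 50% and 93.3% of those matched on score, a share that 8 of 10000 matched draws fell to. On the arms it was 17 of 23, beside 93.6%. The rule set down before the result compared with persistent peaks only and read a share this low as against the hypothesis. A check was added after the result was seen: persistent peaks lie so close to 100% that a higher share could not have been shown. The test thus could not have favoured the hypothesis, so it cannot decide, and beyond the lower share no conclusion is drawn. Random placement of all 0 h CP190 peaks, which the rule did not use, gave 9.69% with Su(Hw), 5.26% with dCTCF and 6.84% with BEAF-32. Su(Hw) was present at 0 h at 12 of the 24, dCTCF at 6 and BEAF-32 at 0.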
